A study of Homo sapiens with 5 samples.

How the data were processed

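RNA of LNCaP cells was extracted with Trizol, turned into biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The 5 arrays fall into 2 celastrol (1.25 µM, 6 h) and 3 DMSO arrays by their titles; the description field of DMSO samples speaks of celastrol, and the title and treatment protocol were followed. The deposited table holds 1 intensity per probe set and array on a linear scale, and RMA is named per the submitters' processing notes, with a version not given in the sources used here. No count or detection call was used. All columns of per-sample values were used, and no control probe set was among the rows. Values were taken as log2(value + 1) with no further normalization. Of 22215 probe sets, 19724 name 1 gene in the platform annotation. The look-up of 19707 of them by Entrez ID changed 0 symbols. A gene is represented by its probe set with the highest mean over all 5 arrays among those naming it alone, which gave 12165 genes.

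The planned test was limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes on all 5 arrays, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Each of 30 gene lists fixed before the data were examined was tested with camera at an inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and each test was adjusted over the lists. With an estimated correlation camera uses the residual degrees of freedom of the fit, 3 on all 5 arrays and 2 on the 4. On the 4 arrays 0 of 30 lists passed in that way, so failing the threshold there does not set 1 list apart from another. The unadjusted p of that test did differ. Among lists past camera at 0.01 it ran from 0.0132 for NRF2 targets to 0.377 for proteasome subunits. The rule for named genes takes the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, or where there are none the 10 of smallest p a direction as values. It adds up to 2 members a list and direction and a fixed set of genes: HSPA1A, HSPA1B, DNAJB1, HSP90AA1, HSF1, HMOX1, DDIT3, KLK3, TMPRSS2, FKBP5, ACTB and GAPDH. Other genes set in that rule were not analysed here. A gene whose probe sets are called in opposite directions was to be named, and 0 were. The part of the rule on list members was written for all 5 arrays, but its genes are named from the 4 arrays alone. This departs from the plan and was decided after seeing that DMSO replicate 3 drove many list members on all 5.

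The fit on 4 arrays was not the planned one. The planned fit called 0 genes, and leaving out DMSO replicate 3, which had been listed beforehand, called 2. Fits of both sets of arrays under other filters, normalizations and variance models were then run and their counts looked at, and the fit that joins the planned dim filter (the 40% of probe sets with the lowest mean over all 5 arrays left out, 13329 kept) to the 4 arrays was taken for the account only after that. The reason was ties, assumed to be commonest among dim probe sets, which was not tested. Over all probe sets, RMA values were identical between arrays for 17.1% to 19.3% in pairs of the 4 arrays. There were 643 probe sets with no variance within either group. A filter on variance was set aside because it selects on the outcome. The 86 genes of that fit are thus a choice made after seeing the data, and the closing section gives every other count. Which list members are above or below 0 does not depend on the threshold.

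Each fit was tested on simulated data with 200 genes kept by the dim filter changed by 0.5, 1 or 2 (log2) in 20 draws, under 3 kinds of noise. The spread was that within groups of the 4 arrays, and DMSO replicate 3 kept its measured offset from the other DMSO arrays. For the comparison of celastrol with DMSO on all 5 arrays (22215 probe sets), which holds that offset, normal noise recovered 0% of changes of 0.5, 8.66% of 1 and 24.2% of 2. On the 4 arrays with the dim filter (13329 probe sets) it recovered 29.6%, 60.4% and 85.1%, and 2.35% of calls were false. Where each probe set's measured ties within groups were kept, 37.2%, 63.5% and 88.2% were recovered and 20% of calls were false, above what the threshold of 0.05 intends. Noise drawn with random sign from the 2 measured replicate differences of each probe set gave 81.6% false calls; with so few values a draw often has no variance within groups, and it called a median of 611 probe sets with no change at all, where both other kinds called 0. Ties remained after the filter: of the 8108 genes tested 2224 had tied values in 1 group and 142 in both, and of the 86 called 5 and 0. The replicate numbers did not pair the arrays: over probe sets, the difference of celastrol replicates 1 and 2 correlated with that of DMSO replicates 1 and 2 at r = -0.0197.

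Alternatives listed before the data were examined covered filters on dim and flat probe sets, quantile, median and cyclic loess normalization, log2(value + 16), trend and robust variance, array weights, the mean of a gene's probe sets, a replicate block, each array left out, and stricter thresholds. The same settings on the 4 arrays were added after seeing the data. No rule for leaving out an array was applied to groups of 2 and 3. No dates or batches were given in the sources used here.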

Results

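The study measured messenger RNA in LNCaP cells, an androgen-responsive human prostate cancer cell line, after 6 h with celastrol, a triterpenoid compound from thunder god vine, or with its solvent DMSO. Celastrol was given at 1.25 µM. There were 5 arrays, 2 of celastrol-treated and 3 of DMSO-treated cells, and the labels call the arrays of each group biological replicates. Each array gave an intensity for 22215 probe sets, of which 19724 name 1 gene, 568 name several and 1923 are unnamed here. Total intensity ranged from 4939400 on DMSO replicate 3 to 5348500 on celastrol replicate 1. The number of arrays limits the precision of every value below. Levels are log2(intensity + 1), and changes are celastrol minus DMSO on that scale, which understates the change of dim genes.

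The array labelled DMSO replicate 3 differed from the other 4. Across probe sets its Pearson correlation with each of them was between 0.843 and 0.844, while the other 4 correlated with one another at 0.994 to 0.998. Between 3908 and 3994 probe sets lay at least 2-fold apart from it in each pair, against at most 109 in pairs of the other 4. Of 14 measured markers of luminal prostate epithelium, 13 were over 2-fold lower on it than on the mean of the others, and the list's median level was 4.56 there against 9.12 to 9.26 elsewhere. KLK3, which encodes prostate-specific antigen, and FOLH1, which encodes prostate-specific membrane antigen, stood at 4.56 and 4.43 on it against means of 10.8 and 12.8 on DMSO replicates 1 and 2. Of 14 measured leukocyte markers, 4 were over 2-fold higher on it, and so were 17 of 19 interferon response genes. Results are therefore given for all 5 arrays, as planned before the data were examined, and then without this array.

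**Figure D1:**
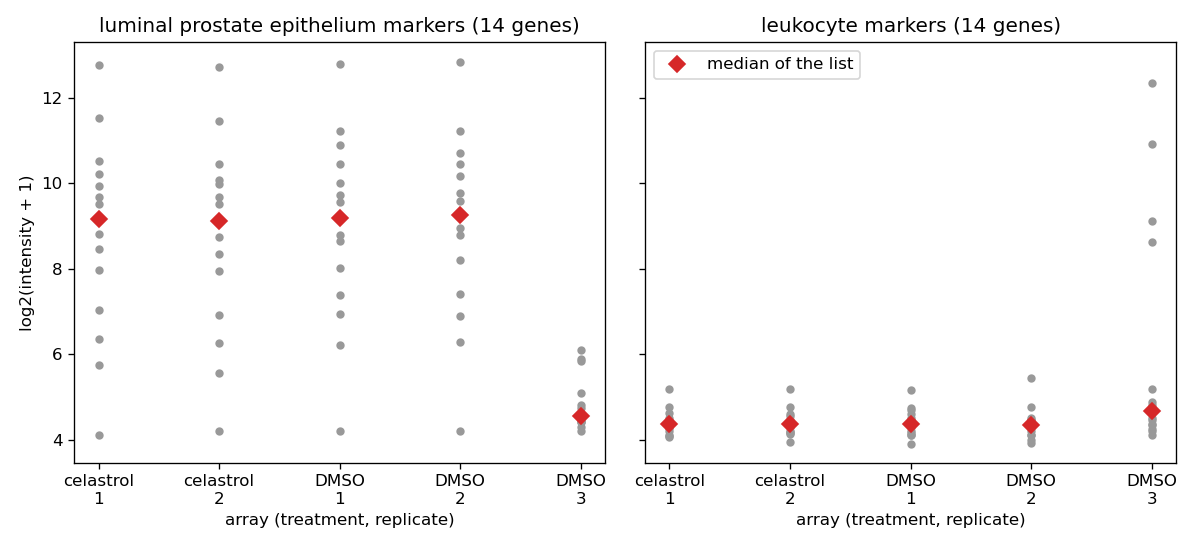
Level of each gene (grey points) in the fixed lists of luminal prostate epithelium markers (left) and leukocyte markers (right), with the list median (red), on each of the 5 arrays, as log2(intensity + 1). The luminal median is 4.56 on DMSO replicate 3 and at least 9.12 on the other 4 arrays, and 4 of the 14 leukocyte markers are over 2-fold higher on DMSO replicate 3.

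The comparison implied by the design asks which transcripts differ between celastrol and its solvent after 6 h. On all 5 arrays, genes for heat shock proteins and their partners were among those with the smallest p on the higher side, although no gene passed the threshold. STIP1, a cochaperone that links HSP70 and HSP90, was higher by 1.03 (SE 0.0747), and CHORDC1 by 1.06 (SE 0.0961). HSP90AA1, an inducible HSP90, was higher by 0.83 (SE 0.0764), HSPA8 by 0.55 (SE 0.0636) and DNAJA1 by 0.89 (SE 0.102). The other 5 of the 10 genes with the smallest p on that side were MANF, at 0.67, HMGCS1, at 0.93, NFX1, at 0.56, IL6R, at 0.95, and AKR1C1, at 1.90. On the lower side the 10 with the smallest p were GLUD1 at -0.73, KIAA0930 at -0.65, PPIF at -0.62, MRPS27 at -0.40, GINS1 at -0.48, RCC1L at -0.64, MAPRE2 at -0.71, ELAC2 at -0.39, REXO4 at -0.44 and PIK3R1 at -0.61. DMSO replicate 3 enters the spread of DMSO here, so a small p favours genes for which it lay near the other DMSO arrays. STIP1 stood at 9.44 on it against a mean of 9.31 on DMSO replicates 1 and 2. HSPA1B stood at 5.78 against 8.98, and its change of 3.43 had an SE of 1.21. The limma test with Benjamini-Hochberg adjustment called 0 of 12165 genes, with a smallest adjusted p of 0.82. An unadjusted limma p under 0.05 was found for 625 probe sets, where chance gives 1111.

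Gene lists fixed before the data were examined did differ on all 5 arrays. By limma's camera test, 12 of 30 lists passed, 8 higher and 4 lower. The heat shock response had a median change of 0.81, with 22 of 25 measured members above 0 and 15 of them past the threshold when adjusted over the list alone (camera adjusted p = 6.02e-23, and adjusted p = 0.0437 with an estimated correlation). It was the one list that held with an estimated correlation. NRF2 targets and antioxidant genes had a median of 0.94, ATF4 and integrated stress response genes 1.09, endoplasmic reticulum chaperones 0.33 and HSP90 cochaperones 0.38. The median was 0.55 for metallothionein and zinc response genes, 0.18 for autophagy and lysosome genes and 0.03 for cholesterol biosynthesis genes. Without DMSO replicate 3 the medians of NRF2 targets, ATF4 genes, HSP90 cochaperones and metallothionein and zinc response genes shrank to 0.56, 0.57, 0.23 and 0.15. Cholesterol genes lost the call in 3 of 5 cases with 1 array left out. S phase genes had a median of -0.60, G2/M genes -0.32, splicing factors -0.14 and interferon response genes -0.94, but without DMSO replicate 3 these medians moved to -0.28, -0.01, -0.04 and -0.09 and that of autophagy and lysosome genes to 0.01, and of these 5 lists S phase genes alone still passed. With an estimated correlation the adjusted p of these 11 lists lay between 0.0908 and 0.872. The correlation itself was estimated at 0.645 for S phase, 0.58 for G2/M and 0.973 for interferon response genes, against -0.0295 for the heat shock response. For the other 18 lists the camera adjusted p ran from 0.0525 to 0.865, the lowest that of NF-kB targets, which passed under some other settings.

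Without the array labelled DMSO replicate 3, and with the dimmest 40% of probe sets left out, single genes of protein folding and oxidative stress rose with celastrol, although the lists of heat shock and NRF2 genes did not hold with an estimated correlation (adjusted p = 0.199 for both). On these 4 arrays 0 of 30 lists passed that test, which has 2 residual degrees of freedom here. HMOX1, the inducible heme oxygenase, rose most, from 6.15 ± 0.247 (SD, n = 2) to 12.1 ± 0.217 (SD, n = 2), a 61.4-fold change. The heat shock genes HSPA1B, BAG3, DNAJB1 and HSPH1 rose 5.15-fold, 4.81-fold, 4.62-fold and 4.48-fold. CBR3, a carbonyl reductase, rose 5.31-fold, GDF15, a stress-induced cytokine, 4.43-fold, DDIT3, which encodes the stress transcription factor CHOP, 4.13-fold, AKR1C1, an aldo-keto reductase, 3.30-fold, and SLC7A11, the cystine transporter, 3.27-fold. On the other side CYP1A1, a target of the aryl hydrocarbon receptor, fell by 1.95 on the log2 scale to 4.61, near the floor, which can understate the fall. The Notch ligand JAG1 fell by 1.65 and the kappa opioid receptor gene OPRK1 by 1.52. SESN1 fell by 1.22, ZBTB43 by 1.18, EFNB2 by 1.17, PRR15L by 1.15, LTN1 by 1.13, PDE9A by 1.10 and PEG3 by 1.09. These 20 genes had standard errors between 0.0266 and 0.187 and limma adjusted p between 0.0238 and 0.0479.

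In that fit 86 of 8108 genes passed the threshold, 47 higher and 39 lower, of which 25 and 14 changed at least 2-fold. This count was chosen after the counts of other settings had been seen. Without DMSO replicate 3 but with no filter, as planned, 2 genes passed, DNAJB1 higher and JAG1 lower. Over 28 other settings the count ran from 0 to 788, and it was 0 when any 1 of the 4 arrays was left out, where few degrees of freedom remain and the change of HMOX1 stayed between 5.77 and 6.12. In simulated data of this fit the share of false calls was 2.35%, 20% or 81.6%, depending on the noise assumed. On all 5 arrays, which include these 4, 17 of the 86 genes had the opposite sign, all of them among the 39 lower. The celastrol arrays lay on 1 side of both DMSO arrays for 34.4% of all genes, where chance without ties gives 33.3%. Tied values count as overlap here, so with ties chance gives less. On the 4 arrays with the dim filter, 2508 of 13329 probe sets had an unadjusted limma p under 0.05, where chance gives 666.

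**Figure D2:**
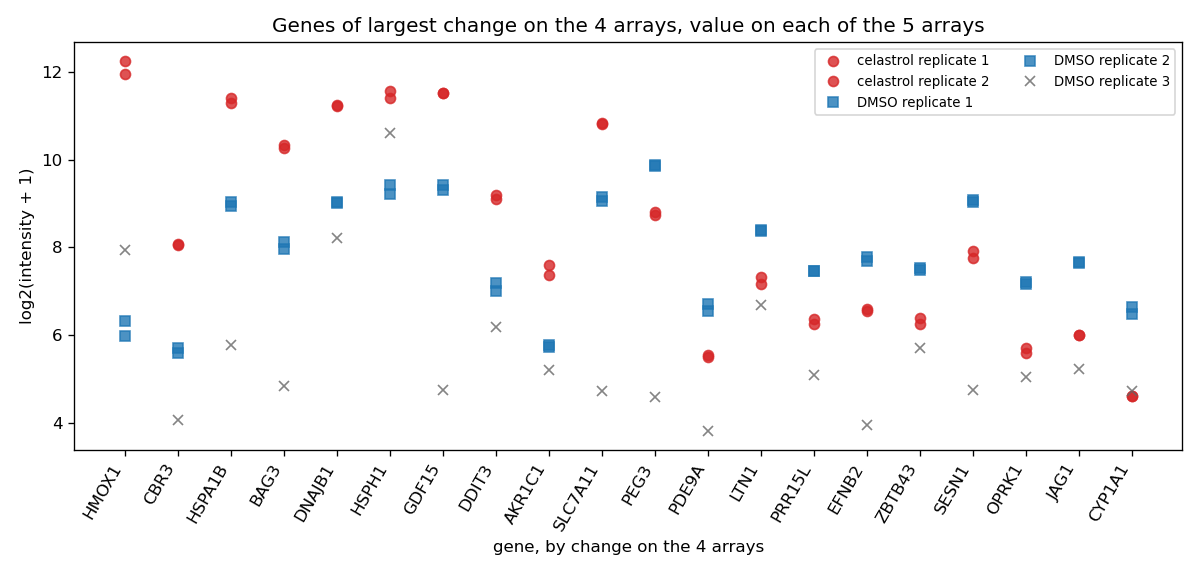
Level of the 20 genes with the largest changes on the 4 arrays, as log2(intensity + 1), on celastrol (red circles), DMSO replicates 1 and 2 (blue squares) and DMSO replicate 3 (grey crosses), each point 1 array. HMOX1 stands at a mean of 12.1 on the celastrol arrays and 6.15 on DMSO replicates 1 and 2, while DMSO replicate 3 lies apart for most genes.

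Of the 25 measured heat shock response genes, 8 rose, 0 fell and all 25 had changes above 0, with a median of 0.73 and 22 higher when adjusted over the list alone (camera adjusted p = 1.46e-21, and adjusted p = 0.199 with an estimated correlation). HSPA1B rose by 2.37 (SE 0.0599) and BAG3 by 2.27 (SE 0.0746). HSP90AA1 stood 0.86 higher without passing (adjusted p = 0.0634), although 2 of its other probe sets passed with 0.58 and 0.64 (limma adjusted p = 0.0458 and 0.0369). The probe set of HSPA1A alone was near the floor, at 4.17 with celastrol and 4.14 with DMSO. It passed the dim filter on a mean that includes 7.51 on DMSO replicate 3. Its change of 0.03 is among the 25 above 0, but ran from -0.0196 to 0.0838 with 1 array left out. The probe set that HSPA1A shares with HSPA1B rose by 3.50 (SE 0.0513, limma adjusted p = 0.0238). HSF1, the transcription factor behind this response, differed by 0.01 (SE 0.0398). Among 12 HSP90 cochaperones 2 rose, STIP1 by 1.07 and PPID by 0.73, and 4 were higher and 2 lower when adjusted over the list alone. The list passed camera (adjusted p = 0.0169, and adjusted p = 0.312 with an estimated correlation), but lost the call whichever of the 4 arrays was left out. It shares STIP1, CHORDC1, FKBP4 and AHSA1 with the heat shock list, so it is not a separate result. Of 21 NRF2 targets 4 rose and 17 were higher when adjusted over the list alone, with a median of 0.89 (camera adjusted p = 3.7e-14, and adjusted p = 0.199 with an estimated correlation). HMOX1 and AKR1C1 led them. The estimated correlation of NRF2 targets was -0.0285, below the fixed 0.01, yet their unadjusted camera p went from 3.7e-15 to 0.0132. Correlation between genes thus does not account for that loss in this list.

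Of 23 genes of the ATF4 and integrated stress response, 6 rose and 20 were higher when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 1.19e-18, and adjusted p = 0.199 with an estimated correlation). DDIT3 rose by 2.05 (SE 0.0927) and DDIT4, an inhibitor of mTORC1 signalling, by 1.57 (SE 0.0575). Among 19 endoplasmic reticulum chaperones 5 rose and 12 were higher when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 2.12e-11, and adjusted p = 0.207 with an estimated correlation). DNAJB9 rose by 1.25 and SDF2L1 by 0.82. In cholesterol biosynthesis 2 of 17 genes rose, INSIG1, a regulator of SREBP processing, by 1.36 and the sterol enzyme MSMO1 by 1.04, and 6 were higher when adjusted over the list alone (camera adjusted p = 5.4e-08, and adjusted p = 0.199 with an estimated correlation). Among 15 immediate-early genes ZFP36 rose by 1.05 and DUSP1 by 0.71, 6 were higher when adjusted over the list alone, and the list's median was 0.17 (camera adjusted p = 1.33e-05, and adjusted p = 0.207 with an estimated correlation).

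Of 25 androgen-induced genes, 1 fell and 13 were lower when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 1.17e-05, and adjusted p = 0.284 with an estimated correlation). TMPRSS2, an androgen-regulated protease gene, fell by 1.08 (SE 0.0477). Its other probe set was near the floor, at 4.74 with celastrol and 4.91 with DMSO. There the change was -0.17 (limma adjusted p = 0.571). KLK3 stood 0.65 lower, a change of -0.65 with adjusted p = 0.106, and FKBP5 had a change of -0.51 with adjusted p = 0.0816. On all 5 arrays, where DMSO replicate 3 holds luminal genes at low levels, the list's median was 0.08 and KLK3 had a change of 1.43 (SE 2.35). Of 12 androgen-repressed genes 3 fell, among them OPRK1 and PEG3, and 5 were lower when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00137, and adjusted p = 0.284 with an estimated correlation). On all 5 arrays that list's median was 0.24. S phase genes had 0 calls among 27, with 13 lower and 1 higher when adjusted over the list alone and a median of -0.28 (camera adjusted p = 6.34e-06, and adjusted p = 0.312 with an estimated correlation). MCM7 and GINS1 had the smallest p there, with changes of -0.40 and -0.45.

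A further 4 lists passed camera with small medians. Metallothionein and zinc response genes had 0 calls among 8, 4 higher when adjusted over the list alone and a median of 0.21 (adjusted p = 0.000618, and adjusted p = 0.392 with an estimated correlation). The metallothionein gene MT1G stood at 0.31 and MTF1, listed for the zinc response, at 0.61. The p53 targets had 4 higher and 1 lower when adjusted over the list alone and a median of 0.20 (adjusted p = 0.00128, and adjusted p = 0.462 with an estimated correlation), but the 1 member called among 16 was SESN1, a stress-induced regulator of mTORC1, which fell. Proteasome subunits had 0 calls among 28, also over the list alone, and a median of 0.04 (adjusted p = 0.017, and adjusted p = 0.763 with an estimated correlation), with PSMD12 at 0.19 and PSMD4 at 0.17. Histones had 0 calls among 11, 2 lower when adjusted over the list alone and a median of -0.09 (adjusted p = 0.017, and adjusted p = 0.515 with an estimated correlation), with H1-10 at -0.62 and H2BC5 at -0.38. With 1 of the 4 arrays left out, histones lost the call in 3 of 4 cases and proteasome subunits in 2, and the median of p53 targets ran from 0.11 to 0.25. Fry did not call these lists. Its adjusted p was 0.113 for metallothionein and zinc response genes, 0.224 for p53 targets, 0.364 for proteasome subunits and 0.0829 for histones. The estimated correlations, in the same order, were 0.246, 0.174, 0.224 and 0.158, above the fixed 0.01. The other lists that passed camera on the 4 arrays also passed fry.

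**Figure D3:**
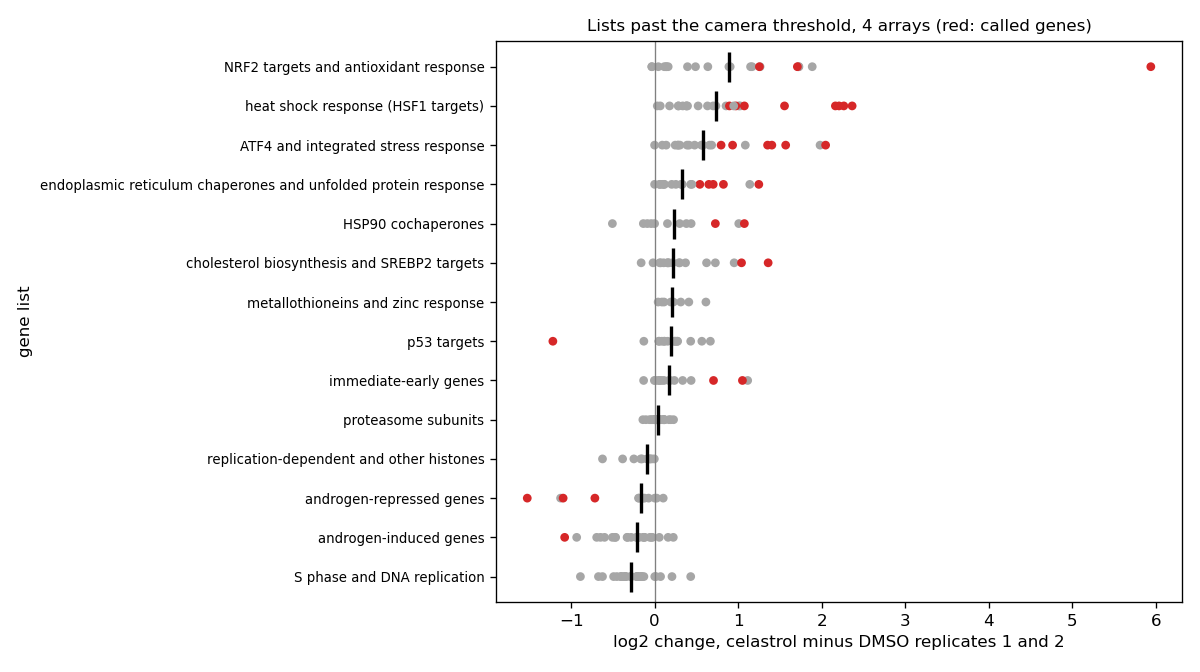
Changes (celastrol minus DMSO replicates 1 and 2, log2 scale) of the members of the 14 lists that passed camera on the 4 arrays, 1 point a gene, red where the gene was called, with the list median as a black bar. All 25 heat shock genes lie above 0, and 22 of 25 androgen-induced genes lie below it.

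The other 16 lists did not pass, with camera adjusted p from 0.241 to 0.846. They were NF-kB targets, apoptosis regulators, G2/M, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, splicing factors, autophagy and lysosome, polyamine metabolism, interferon response, and the markers of luminal, basal, neuroendocrine, fibroblast, leukocyte and endothelial cells. Their members of smallest p had changes of -0.46 for NFKBIA and -0.40 for SOD2, -0.21 for BCL2L1 and 0.25 for TNFRSF10B, -0.32 for KIF2C and -0.18 for PLK1, 0.64 for VEGFA and -0.20 for EGLN3, -0.18 for ATP5F1B and -0.17 for SDHD, -0.11 for RPS9 and 0.10 for RPL14, and -0.28 for SRSF6 and -0.19 for SRSF10. In the next lists they were 0.24 for WIPI1 and 1.26 for SQSTM1, -0.29 for AMD1 and -0.26 for ARG2, and -0.23 for OAS3 and -0.13 for IFIT1. For cell type markers they were 0.16 for CD44 and 0.33 for DST, -0.13 for ENO2 and 0.04 for SYP, 0.12 for TAGLN and 0.04 for VIM, -0.29 for MS4A1 and 0.12 for CD79A, and 0.03 for TEK, while TMPRSS2 was the called luminal marker. CD44, MS4A1 and CD79A were near the floor on the 4 arrays. They passed the dim filter because its mean includes DMSO replicate 3, where they stood at 8.88, 10.9 and 8.63. ACTB and GAPDH, used as reference genes, had changes of -0.10 (SE 0.0419) and 0.01 (SE 0.0268). Of the 16 lists, NF-kB targets alone passed fry, on the lower side (adjusted p = 0.0461). Of the 14 lists that passed on the 4 arrays, 8 also passed on all 5, each in the same direction, although the fits share these 4 arrays. Median and test differed in sign for 1 list in either fit, fibroblast markers on the 4 arrays and oxidative phosphorylation on all 5.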

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

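Leaving out DMSO replicate 3 with no filter and the settings of all 5 arrays were planned; the filter on the 4 arrays and every other setting of them were chosen after seeing the data. On all 5 arrays the count of called genes stayed at 0 under every filter, normalization, scale, trend and threshold tried and with the mean of probe sets, but array weights, which gave DMSO replicate 3 a weight of 0.045, called 45 genes (34 higher, 11 lower), 33 of them among the 86, which rest on 4 of the same arrays. With 1 array left out the count ran from 0 to 2, the 2 coming without DMSO replicate 3; a lone array of a group is assumed to vary like the other group. Camera passed 12 lists, 10 to 15 under other settings (10 to 14 with 1 array left out), but 1 with an estimated correlation and 2 by fry. For celastrol versus DMSO, 4 arrays, the 86 genes became 2 with no filter, 0 on all 5 arrays with the same filter, 788 with the filter on variance, 272 with quantile normalization, 194 with median centring, 223 with cyclic loess, 145 with trend and robust variance, 161 with the mean of probe sets, 0 at an adjusted p under 0.01 and 39 at 2-fold or more. The 86 genes were all among the 788, 272, 194 and 223. With no filter, trend gave 1, trend and robust variance 1, array weights 2 and log2(value + 16) 28. Leaving out any 1 of the 4 arrays gave 0, where 1 residual degree of freedom remains and few calls can pass, but the changes stayed at 5.77 to 6.12 for HMOX1, 2.20 to 2.22 for DNAJB1 and -1.66 to -1.65 for JAG1. The other 7 of the 28 settings stayed within 1.5 times: 126 without probe sets of no variance within groups, 94 with log2(value + 16), 87 with array weights, 83 with the dim filter on the 4 arrays' own mean, and 124, 91 and 103 with no filter and quantile normalization, median centring or cyclic loess. Under the filter on variance the split of celastrol versus DMSO, 4 arrays, genes higher, and of celastrol versus DMSO, 4 arrays, genes lower, went from 47 and 39 to 329 and 459. The cause was not tested. The lists on the 4 arrays numbered 14, and 11 to 15 under other settings and by fry (11 to 13 with 1 array left out), but 0 with an estimated correlation. With 1 of the 4 arrays left out, HSP90 cochaperones lost the call in all 4 cases (median 0.132 to 0.322), histones in 3 (-0.18 to -0.0558) and proteasome subunits in 2 (0.0146 to 0.0555), and p53 targets kept it with medians of 0.112 to 0.247. With 1 of all 5 left out, splicing factors, autophagy and cholesterol genes each lost it in 3 cases, and G2/M and interferon genes in 1, the case without DMSO replicate 3.

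With a replicate block on arrays 1 and 2 of each group, 0 genes were called, with the dim filter and without it, also with trend and robust variance; fewer residual degrees of freedom remain, and the numbers do not pair the arrays. Camera passed 13 lists of all probe sets and 14 of those kept by the filter. The block turned androgen-induced genes to -0.185, androgen-repressed genes to -0.163, HSPA1A to 0.0321, HSF1 to 0.0119, KLK3 to -0.648 and GAPDH to 0.0099 against all 5 arrays, as it leaves out DMSO replicate 3.

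Against all 5 arrays, array weights turned androgen-induced genes to -0.197, androgen-repressed genes to -0.132, HSPA1A to 0.0128, HSF1 to 0.000534, KLK3 to -0.61 and GAPDH to 0.0102, and median centring put androgen-induced genes at 0.103, with the test on the other side, and GAPDH at 0.00653. Leaving out 1 array gave ranges of -0.185 to 0.359 for androgen-induced genes, -0.163 to 0.537 for androgen-repressed genes, -1.68 to 0.0321 for HSPA1A, -0.105 to 0.0119 for HSF1, -0.648 to 2.51 for KLK3, -1.08 to 0.422 for TMPRSS2 and -0.0318 to 0.0099 for GAPDH. For the 4 arrays, bringing DMSO replicate 3 back turned androgen-induced genes to 0.152, androgen-repressed genes to 0.243, histones to 0.126, SESN1 to 0.219, EFNB2 to 0.0979, PEG3 to 0.662, ATP5F1B to 0.124, SRSF6 to 0.0592, H1-10 to 0.134, WIPI1 to -0.036, AMD1 to 0.704, ARG2 to 1.41, CD44 to -1.36, DST to -0.157, ENO2 to 0.019, VIM to -0.859, CD79A to -1.34, HSPA1A to -1.09, HSF1 to -0.0535, KLK3 to 1.43 and GAPDH to -0.0165. The filter on variance put SYP, 4 arrays, at -0.0987, and the mean of probe sets put it at -0.0681, TAGLN, 4 arrays, at -0.21, HSF1, 4 arrays, at -0.114 and GAPDH, 4 arrays, at -0.00502. Leaving out 1 of the 4 arrays gave -0.0196 to 0.0838 for HSPA1A, -0.0259 to 0.0496 for HSF1 and -0.00831 to 0.0819 for SYP. Without a change of sign it also moved by over 1.5 times the values of DST (0.182 to 0.475), TAGLN (0.0474 to 0.186), CD79A (0.0807 to 0.168), TEK (0 to 0.0664), ACTB (-0.142 to -0.0595) and GAPDH (0.00419 to 0.0156). Of the 30 called genes named, 27 kept their sign in every setting run for single genes, and 208 of their 480 values under these settings lost the call. Of 224 such values of the 14 lists, 205 kept direction and side. Lists that did not pass are counted here without androgen-induced and androgen-repressed genes on all 5 arrays, which are given above. The counted lists changed sign in 25 of 255 values on the 4 arrays and 43 of 240 on all 5, and passed the threshold in 7 and 21 of them. NF-kB targets on all 5 arrays were among these, with adjusted p = 0.0134 under the dim filter and 0.00641 under the filter on variance, but 0.933 without DMSO replicate 3. Intensities near the floor, at about 4, limit what dim genes can show.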

Other observations

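All tests in this part were chosen after the values had been seen, and the lists of this paragraph were written because of genes that stood out. On the 4 arrays, amino acid transporter genes had a median change of 0.40, with 10 of 11 above 0 and 2 called higher (camera adjusted p = 3.39e-08, and adjusted p = 0.125 with an estimated correlation). Aldo-keto and carbonyl reductases had a median of 0.49, with 2 of 7 called higher (camera adjusted p = 0.00273, and adjusted p = 0.125 with an estimated correlation). Of 29 measured DNAJ genes 5 were called higher and 1 lower, with a median of 0.06 (camera adjusted p = 0.000338, and adjusted p = 0.125 with an estimated correlation). FOXO targets had a median of -0.14, with 2 of 16 called lower (camera adjusted p = 0.00301, and adjusted p = 0.125 with an estimated correlation). JAG1 and CYP1A1 were each the 1 called member of their lists, 11 Notch genes (camera adjusted p = 0.665) and 5 aryl hydrocarbon receptor targets (camera adjusted p = 0.472).

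The array labelled DMSO replicate 3 stood apart from the other 4, and a mixture in which LNCaP RNA kept a share of at least 5% is argued against by 10 luminal markers with a mean of at least 8 on DMSO replicates 1 and 2, which stood at a median of 3.5% of that level, FOLH1 at 0.298% and AMACR at 14.7%. Most were near the floor, so these are upper bounds, and a smaller share of LNCaP RNA is not excluded. A failed hybridisation or faulty normalization is argued against by 202 probe sets at least 16-fold above every other array, against 0 on any other. RNA of another cell type, of the B lymphocyte kind, in place of LNCaP RNA stays open as a candidate explanation: a list of 14 measured B lymphocyte markers, 2 of them also in the leukocyte list and 0 above 6 on the other arrays, was higher by a median of 4.14, with CD74 at 13.1, POU2AF1 at 11.0 and MS4A1 at 10.9, while the T lymphocyte, myeloid and erythroid lists differed by medians of 0.0748, 0.0898 and -0.0197. The list was written after some of these genes had been seen, and which sample the RNA came from was not tested.

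Androgen-induced genes were lower with celastrol on the 4 arrays, with 22 of 25 below 0, 1 called and a median of -0.207, but the list did not hold with an estimated correlation (adjusted p = 0.284). A general fall of genes of the same intensity is argued against by 10000 random lists matched on intensity, of which 0 had a median as low (0.01% with 1 added to both counts, the lowest value this test can give). The middle of the random medians was -0.0227. The androgen-induced list had already passed camera on these arrays, and the draws take genes as independent. The share is thus no test of chance. A general loss of short-lived transcripts stays open, as the immediate-early genes, with a median of 0.172, passed camera on the higher side, though not with an estimated correlation (adjusted p = 0.207), and so cannot show it. A loss of androgen signalling alone would raise androgen-repressed genes. They had a median of -0.163, with 9 of 12 below 0, 3 called lower and 0 called higher. Camera (adjusted p = 0.00137) and fry (adjusted p = 0.00464) put them lower on these 4 arrays, which argues against such a loss as the sole effect. Their test with an estimated correlation (adjusted p = 0.284) cannot decide, as 0 of 30 lists passed it on the 4 arrays. A loss of androgen signalling beside other effects of celastrol stays open. On all 5 arrays neither list was lower.

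The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split called 86 genes, the highest of the others 0, and 1 split, the real one, called as many.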
